A study of Synechocystis sp. PCC 6803 with 10 samples.

How the data were processed

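Total RNA from cultures of Synechocystis was measured on 10 single-colour Agilent arrays: 3 control arrays, 3 without iron (0Fe), 2 without manganese (0Mn) and 2 without both (0Fe0Mn). Per the labels, cells were washed in a buffer with EDTA and grown for 2 days of limitation. The control medium held 10 µM iron and 1 µM manganese. The 0Fe medium held no added iron and 50 µM desferrioxamine B, a siderophore that binds iron; manganese was left out of the 0Mn medium, and 0Fe0Mn held the siderophore and neither metal. The labels do not state the time point of the control or the siderophore concentration of 0Fe0Mn. They also state that 1 of 3 replicates of 0Mn and of 0Fe0Mn was left out by the authors because it deviated strongly; these arrays were not analysed here. The labels do not say whether the samples of a group came from separate cultures, so p-values measure the spread between the samples kept alone. Leaving out deviating replicates can narrow that spread. All 3 controls lay on 1 slide and both 0Fe0Mn arrays on another, so the spread within these groups held no difference between slides. Fitted as a random block, the slide gave a correlation of 0.613 within slides, which the main p-values do not allow for.

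Spot intensities were read with Agilent Feature Extraction 10.7.3.1, which subtracted a background surface, corrected for position on the array and replaced low values with a surrogate, with no scaling between arrays, per the file headers. RNA was labelled directly, without synthesis of cDNA, per the labels' protocols, so the signal is specific to the strand. The log2 values of the deposited series table were made by the authors with limma, per the submitters' processing notes, which give no version or step. From the values themselves, their columns had close medians (11.49 to 11.52), matched log2 of the mean spot signal (r 0.993 to 1.00) and held no background subtraction. That table served as an alternative, and 0 columns of per-sample values went unused.

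Each array held 40886 spots and 20363 probes for 8830 features, with a median of 2 spots per probe. Median processed signal was 1237, 1318 and 979.8 in the controls, 1967, 1808 and 1261 in 0Fe, 810 and 1453 in 0Mn and 2050 and 1799 in 0Fe0Mn. The share of spots well above background was 79.0% to 95.3%, which limits what can be said of dim features. Duplicate spots would give a spread of 0.108 to 0.168 between replicate arrays, and the observed robust standard deviation of replicate pairs was 0.161 to 0.438.

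The processed signal was put on a log2 scale and the array's 75th percentile over non-control spots was subtracted. Spots marked as outliers by the scanner software were left out, and spots were averaged per probe. A probe was kept if it was well above background on all arrays of at least 1 group (18003 probes), and a feature was the mean of its kept probes. After 1 feature with a missing value was dropped, 8366 features were tested, 3319 of them genes. Where a feature was at background throughout a group, its fold is given as at least the fold over each array's lowest signal well above background. Where some probe was well above background but the mean over probes lay below that signal on every array of a group, the value of the brightest probe is given as well. Of the 3356 locus tags of genes on the array, 0 matched the reference given, so symbols and functions come from general knowledge, fixed with the gene lists before the data were examined. Probe sequences are shared by 733 features, which include 59 genes that share one with another gene, psbA2 among them. The regulatory RNA IsaR1 was not named on the array.

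Comparisons were made with limma 3.58.1 in R 4.3.3 (statmod 1.5.0, and data.table at version 1.17.8), with a single fit of 4 group means to all 10 arrays and moderated t-tests, so that groups of 2 share the estimate of the spread with the others. P-values were adjusted by Benjamini and Hochberg's method over all tested features, and a feature passed at adjusted p under 0.05. Values after ± are standard errors of that fit. The interaction is the change from 0Fe to 0Fe0Mn minus the change from control to 0Mn. A total of 24 gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over all lists and comparisons, beside camera with an estimated correlation and fry.

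Named genes followed a rule set before the data were examined: in comparisons with control up to 8 genes and 4 other transcripts each way with the largest change among those that passed and whose arrays did not overlap, in the others up to 5 genes each way, up to 4 members of each list, and a fixed set of iron, manganese and photosynthesis genes. Members named beyond this rule are said to be so.

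The scripts were tested on simulated data with known changes in 200 of 8366 features. Of changes of 1 log2 unit 76% were recovered for 0Fe against control, 67% for 0Mn, 73% for 0Fe0Mn, 78% for 0Fe0Mn against 0Fe, 59% for 0Fe0Mn against 0Mn and 46% for the interaction, with 4 to 10 false calls among 8166 unchanged features. The simulated noise held no slide effect, whereas slides went with groups in the data, so these rates hold only without such an effect. Alternatives set before the data were examined covered scaling (median, quantile), background (normexp with an offset of 50), the deposited table, probe filters, the brightest probe, array weights, a trended robust variance, the arrays fitted, the slide as a fixed or random block, the replicate number as a block and each array left out. Leaving out 0Fe 1 with 0Mn 2, and leaving out slide 2, were added after the data were seen.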

Results

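The data are transcript levels in the cyanobacterium Synechocystis, a unicellular photosynthetic bacterium, grown with or without iron and manganese. Each of 10 single-colour arrays measured the total RNA of 1 culture sample. The groups were 3 control arrays, 3 arrays without iron (0Fe), 2 without manganese (0Mn) and 2 without both metals (0Fe0Mn). Median processed signal per array ran from 810 in 0Mn 2 to 2050 in 0Fe0Mn 1. The share of spots well above background ran from 79.0% in control 2 to 95.3% in 0Fe 1, and no spot was saturated. Of 8366 transcripts tested, 3319 were genes and 5047 were other transcripts, such as antisense RNAs, 5' untranslated regions and transcripts that start inside a gene. Changes are given in log2 units with their standard error, written after ±, and n gives the arrays of each group.

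The first component of the 10 arrays held 64.4% of the variance, and the second held 18.1%. Arrays without iron lay apart from arrays with iron on the first. The arrays came from 3 slides: slide 1 held control 1, 2 and 3 and 0Fe 1, slide 2 held 0Fe 2, 0Fe 3 and 0Mn 2, and slide 3 held 0Mn 3 and both 0Fe0Mn arrays. The array 0Fe 1 stood apart from its group: across transcripts, which are not independent replicates, its r was 0.992 with the 0Fe0Mn mean and 0.970 with the mean of 0Fe 2 and 0Fe 3. Within 0Fe the inorganic carbon uptake list differed most between the slides, with a median 1.88 higher in 0Fe 2 and 0Fe 3 than in 0Fe 1. Within 0Mn it was 0.12 higher in 0Mn 2 than in 0Mn 3, where phycobilisome degradation (0.83), high-light inducible proteins (0.76) and nitrogen assimilation (0.74) differed more.

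**Figure D1:**
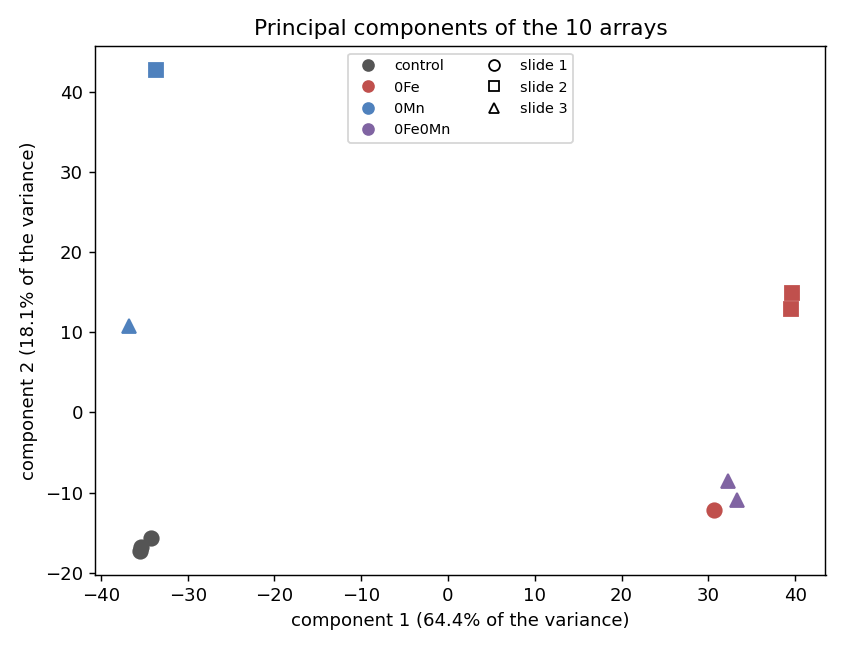
Position of each array on the first and the second principal component of the log2 signals of all tested transcripts, coloured by group and marked by slide. The arrays without iron lie apart from the control and 0Mn arrays along the first component (64.4% of the variance), and 0Fe 1 lies beside the 0Fe0Mn arrays.

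The first comparison asked which transcripts changed when iron was withheld. The media without iron also held the siderophore, so here and below leaving out iron cannot be told apart from adding the siderophore. After 2 days without iron, isiA (sll0247), which encodes a chlorophyll-binding antenna protein of iron-starved cells, rose by 8.78 ± 0.22, a 439.6-fold rise (limma, adjusted p = 8.7e-09, n = 3 and 3). Its antisense RNA IsrR fell by 7.54 ± 0.31 (adjusted p = 1.2e-07). The size of the rise of isiA is uncertain. Its levels in control 1, 2 and 3 (-3.18, -3.44 and -2.69) lay near each array's lowest signal well above background (-3.75, -3.33 and -3.31). The outer membrane receptor gene sll1206 rose by 7.67 ± 0.20 (5.70 by its brightest probe), and the genes of its energising system rose as well: exbB1 (sll1404) by 6.22 ± 0.14 (3.97 by its brightest probe) and tonB (slr1484) by 4.19 ± 0.11. For sll1206 and exbB1 the mean over probes in the controls lay below the lowest signal well above background, termed the floor here, so the size of their rise is uncertain. The brightest probe is given for such genes. Over the same samples the phycobilisome linker gene cpcD (ssl3093) fell by 3.23 ± 0.11 and the photosystem I gene psaF (sll0819) fell by 2.86 ± 0.12.

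All 4 genes of the isi operon list rose in 0Fe, with a median of 6.34 (camera, adjusted p = 2.47e-05; adjusted p = 0.0980 with an estimated correlation). isiB (sll0248), which encodes flavodoxin, an iron-free electron carrier, rose by 7.63 ± 0.16, but no control array showed it above background. Measured against that background its rise was at least 51.0-fold. isiC (sll0249), whose mean in the controls lay below the floor, rose by 5.06 ± 0.14, but by 0.81 with its brightest probe. With isiB at its bound the list median was 5.37. In the same list ssl0461 rose by 1.54 ± 0.14, although its brightest probe alone gave -0.15. Of 22 iron uptake genes 18 rose and none fell (median 2.07, camera adjusted p = 5.04e-11; adjusted p = 0.0912 with an estimated correlation). Among the genes of the Fut transporter for ferric iron, futA2 (slr0513) rose by 3.71 ± 0.16, futA1 (slr1295) by 3.15 ± 0.11, futC (sll1878) by 2.26 ± 0.13 and futB (slr0327) by 0.43 ± 0.11. The ferrous iron transporter gene feoB (slr1392) rose by 3.68 ± 0.14, and exbD1 (sll1405), at background in the controls, rose at least 15.2-fold. Other transcripts followed the isi region: IsiA-2-0-x rose 127.9-fold, IsiA-1-0-x by 6.77 ± 0.18 and isiA-0-x by 6.45 ± 0.14, whereas sll0247-as2, which shares probe sequences with IsrR, fell by 6.89 ± 0.27. The 5' untranslated region of slr1489 was at background in the controls and rose at least 76.2-fold.

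Iron storage moved in no common direction in 0Fe (list median -0.23, mean 0.149, camera adjusted p = 0.965). mrgA (slr1894), a ferritin-like protein gene, rose by 1.08 ± 0.15, whereas the bacterioferritin genes bfrA (sll1341) and bfrB (slr1890) stood at -0.40 ± 0.16 (adjusted p = 0.055) and -0.23 ± 0.12. The ferric uptake regulator gene fur (sll0567) rose by 1.78 ± 0.13 and the repressor gene sufR (sll0088) by 1.10 ± 0.12. Of 7 metal-responsive regulators 4 rose and 1 fell, pfsR (sll1392), by 0.48 ± 0.10 (list median 0.41, camera adjusted p = 0.0772). Iron-sulfur cluster assembly rose in 10 of 11 genes (median 0.82, camera adjusted p = 0.000349; adjusted p = 0.346 with an estimated correlation). sufB (slr0074) rose by 1.77 ± 0.14 and iscS1 (slr0387), below the floor in the controls, by 1.53 ± 0.19 (1.12 by its brightest probe). All 5 genes of manganese uptake and sensing passed as higher by their means over probes (median 0.74, camera adjusted p = 0.0106; adjusted p = 0.336 with an estimated correlation). In the manganese transporter operon mntC (sll1598) rose by 1.66 ± 0.15 and mntA (sll1599) by 0.82 ± 0.17. For mntB (sll1600), below the floor in the controls, the mean over probes stood at 0.74 ± 0.14, but the probes disagreed: its brightest probe gave -1.06 and the deposited matrix -0.18, both of which passed as lower, so its direction stays open. The sensor kinase gene manS (slr0640) rose by 0.41 ± 0.10, with -0.0545 from its brightest probe, and the response regulator gene manR (slr1837) by 0.74 ± 0.15.

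The photosynthetic apparatus fell in 0Fe. All 12 photosystem I genes fell (median -1.28, camera adjusted p = 1.05e-07; adjusted p = 0.303 with an estimated correlation). psaJ (sml0008) fell by 2.64 ± 0.13, psaB (slr1835) by 1.73 ± 0.17 and psaA (slr1834) by 1.19 ± 0.17. In photosystem II 17 of 23 genes fell (median -0.90, camera adjusted p = 0.000289; adjusted p = 0.443 with an estimated correlation). psbC (sll0851) fell by 1.77 ± 0.18 and psbD (sll0849) by 1.59 ± 0.19. The 4 that rose were psbZ (sll1281, 0.96), psbY (sml0007, 0.70), psb28 (sll1398, 0.44) and psb27 (slr1645, 0.35), named here after their values were seen. psbZ and psbY encode small subunits, psb27 and psb28 assembly factors. Extrinsic proteins that shield the manganese cluster fell in 4 of 5 genes (median -1.32, camera adjusted p = 0.00222; adjusted p = 0.303 with an estimated correlation). psbO (sll0427) fell by 2.00 ± 0.12. Phycobilisome genes, which encode the light-harvesting antenna, fell in 12 of 13 cases (median -1.65, camera adjusted p = 2.25e-08; adjusted p = 0.303 with an estimated correlation), cpcC1 (sll1580) by 2.74 ± 0.13. Of 11 genes for cytochrome b6f and electron carriers 7 fell (median -0.61, camera adjusted p = 0.00211; adjusted p = 0.337 with an estimated correlation). petF (ssl0020), which encodes ferredoxin, fell by 1.73 ± 0.14 and petJ (sll1796), the cytochrome c6 gene, by 0.64 ± 0.20. In the ATP synthase list 7 of 9 genes fell, atpI (sll1322) by 1.76 ± 0.11, and atpE (slr1330) rose by 0.64, named after its value was seen (median -0.67, camera adjusted p = 0.0128; adjusted p = 0.583 with an estimated correlation).

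Carbon fixation and carboxysome genes fell in 8 of 8 cases in 0Fe (median -1.26, camera adjusted p = 4.76e-06; adjusted p = 0.217 with an estimated correlation), with rbcS (slr0012), the small subunit gene of Rubisco, down by 2.15 ± 0.12. Inorganic carbon uptake fell in 10 of 14 genes (median -2.19, camera adjusted p = 0.00160; adjusted p = 0.578 with an estimated correlation). Among its bicarbonate transporter genes sbtA (slr1512) fell by 2.40 ± 0.54, cmpA (slr0040) by 2.57 ± 0.53 and cmpB (slr0041), above background on 1 of 3 0Fe arrays, by 4.03 ± 1.02. On slide 1, where 0Fe 1 alone lay beside the controls, the list median was -3.59. Within 0Fe the list stood a median 1.88 higher in 0Fe 2 and 0Fe 3 than in 0Fe 1. Tetrapyrrole synthesis went both ways (median -0.04, camera adjusted p = 0.289). Of 22 genes 7 fell, chlL (slr0749) of the light-independent chlorophyll pathway by 2.77 ± 0.21. The 4 that rose were chlD (slr1777, 1.14), chlG (slr0056, 0.67), hemE (slr0536, 0.55) and hemC (slr1887, 0.40), named after their values were seen. In nitrogen assimilation glnA (slr1756) and gifB (sll1515) rose, and amt1 (sll0108) and narB (sll1454) fell (13 genes, median -0.11, camera adjusted p = 0.860). Superoxide dismutase sodB (slr1516) stood at -0.19 ± 0.20 (adjusted p = 0.44). Further falls by size were slr1634 (5.34 ± 0.17), slr0006 (3.29 ± 0.13), sll0543 (3.12 ± 0.10), slr1214 (3.03 ± 0.52) and sll1240, which was at background in 0Fe and at least 2.13-fold lower. The largest further rises were sll1549 (5.20 ± 0.16, above background on 2 of 3 control arrays) and slr1485, below the floor in the controls (4.97 ± 0.18, or 2.91 by its brightest probe). Among other transcripts slr1634-0-x fell by 6.21 ± 0.27 and NC-1103 by 5.58 ± 0.17.

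In total 1826 of 3319 genes (55.0%) passed in 0Fe against control, 974 higher and 852 lower, of which 199 and 251 changed at least 2-fold. Among other transcripts 2591 of 5047 passed. Probes of the same gene disagreed in sign for 375 of the 1734 passing genes with several probes, against 27 of 475 in 0Mn, 187 of 1323 in 0Fe0Mn and 142 of 1352 in 0Fe0Mn against 0Mn. Adjusted over the list alone, the member counts above were unchanged except for cytochrome b6f (8 lower), inorganic carbon uptake (11 lower and 1 higher), iron storage (1 higher, 1 lower) and nitrogen assimilation (2 higher, 1 lower). With the slide as a block, which equals the contrast on slide 1, 1513 genes passed, 1303 of them in the main set. That contrast rests on 0Fe 1 as its single 0Fe array, the one that stood apart from its group. The blocked list medians were 6.43 for isi, 2.06 for iron uptake, 0.54 for manganese uptake and 0.41 for iron-sulfur assembly. They were -1.19 for photosystem I, -0.96 for photosystem II, -1.41 for the extrinsic proteins, -1.26 for the phycobilisome, -0.48 for cytochrome b6f and -1.35 for carbon fixation. The ATP synthase list no longer passed (median -0.45, adjusted p = 0.126). Blocking ended 9 of 103 calls on named genes, among them petJ (-0.40) and futB (0.43, adjusted p = 0.054). Leaving out a single array ended the calls of petJ, narB, amt1, pstC, tpx, sufA and gpx2 in at least 1 case. The 3 ribosomal RNA features lay between -0.40 and -0.50 without passing, and the 42 transfer RNAs had a median of -0.44.

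**Figure D2:**
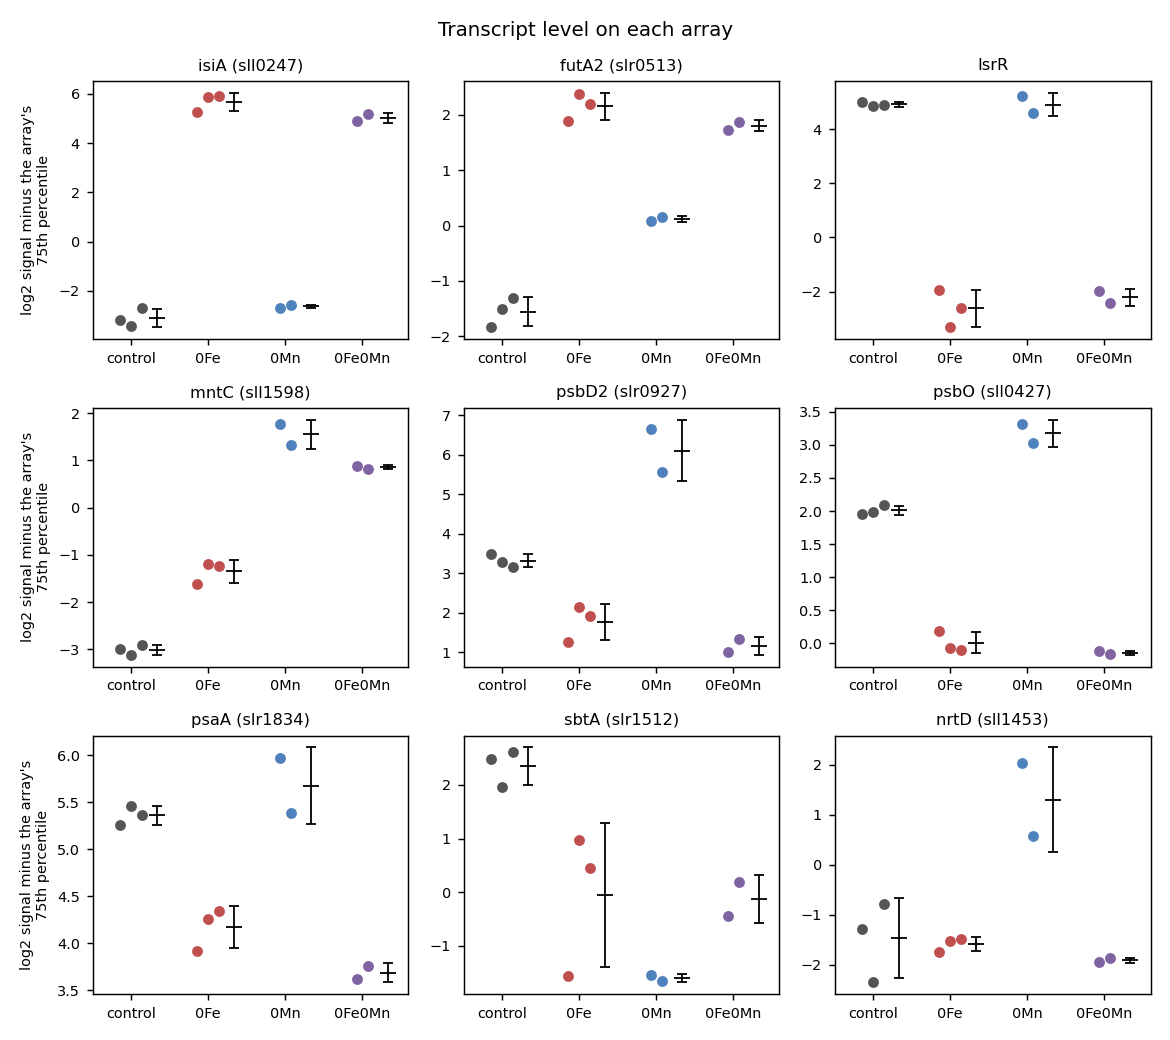
Level of 9 named transcripts in each array, as log2 signal minus the array's 75th percentile, by group; points are arrays and bars give the mean with its standard deviation. isiA is high and IsrR low in both groups without iron, mntC is high in both groups without manganese, and psbD2, psbO and nrtD are highest in 0Mn.

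The second comparison asked the same of manganese. Without manganese the operon of the Mnt transporter rose most: mntB (sll1600) by 4.68 ± 0.15, mntC (sll1598) by 4.56 ± 0.17 and mntA (sll1599) by 4.54 ± 0.19 (limma, adjusted p = 4.9e-07, 9.7e-07 and 1.5e-06, n = 2 and 3). The mean of mntB in the controls lay below the floor, and its brightest probe rose by 1.83. The nitrate transporter gene nrtD (sll1453) rose by 2.77 ± 0.47 and the nitrate reductase gene narB (sll1454) rose by 2.58 ± 0.25. psbD2 (slr0927), a gene of the photosystem II reaction centre protein D2, rose by 2.78 ± 0.33. Genes for the uptake of inorganic carbon fell, and the flavodiiron protein gene flv2 (sll0219), below the floor in 0Mn, fell by 5.28 ± 0.98 (-4.62 by its brightest probe) and the bicarbonate transporter gene sbtA (slr1512) by 3.96 ± 0.60.

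Manganese uptake and sensing rose through its 3 transporter genes in 0Mn (5 genes, median 4.54, camera adjusted p = 0.000985; adjusted p = 0.291 with an estimated correlation), whereas manS (slr0640) stood at -0.07 ± 0.12 and manR (slr1837) at -0.44 ± 0.17 (adjusted p = 0.10). Photosystem II core and assembly rose in 13 of 23 genes (median 0.73, camera adjusted p = 3.78e-09; adjusted p = 0.303 with an estimated correlation). psbD (sll0849) rose by 2.12 ± 0.22 and psbC (sll0851) by 1.58 ± 0.20. The extrinsic proteins of the manganese cluster rose in 4 of 5 genes (median 1.08, camera adjusted p = 0.000881; adjusted p = 0.291 with an estimated correlation). psbO (sll0427) rose by 1.17 ± 0.13 and psbQ (sll1638) by 1.13 ± 0.14. Phycobilisome genes rose in 8 of 13 cases, apcB (slr1986) by 1.00 ± 0.17, and cpcG2 (sll1471), above background on 1 of 2 0Mn arrays, fell by 2.09 ± 0.43 (median 0.62, camera adjusted p = 0.000216; adjusted p = 0.412 with an estimated correlation). In cytochrome b6f and electron carriers 6 of 11 genes rose, petB (slr0342) by 1.39 ± 0.16 (median 0.49, camera adjusted p = 0.000142; adjusted p = 0.303 with an estimated correlation). petF (ssl0020) stood at 0.14 ± 0.16 and petJ (sll1796) at -0.02 ± 0.23, or 0.72 from its brightest probe. Tetrapyrrole synthesis rose in 10 of 22 genes (median 0.44, camera adjusted p = 5.67e-05; adjusted p = 0.382 with an estimated correlation). chlA2 (sll1874) rose by 2.09 ± 0.23 and ho2 (sll1875), a heme oxygenase gene, by 1.90 ± 0.14. Photosystem I rose in 3 of 12 genes (median 0.34, camera adjusted p = 0.0342; adjusted p = 0.589 with an estimated correlation), psaB (slr1835) by 0.67 ± 0.19, and psaA (slr1834) stood at 0.32 ± 0.19. In the ATP synthase list 3 of 9 genes rose (median 0.28, camera adjusted p = 0.00936; adjusted p = 0.579 with an estimated correlation).

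Iron uptake rose in 10 of 22 genes in 0Mn (median 0.23, camera adjusted p = 0.000216; adjusted p = 0.291 with an estimated correlation). futA2 (slr0513) rose by 1.67 ± 0.18, tonB (slr1484) by 1.03 ± 0.13, futA1 (slr1295) by 0.97 ± 0.13, futC (sll1878) by 0.91 ± 0.15 and feoB (slr1392) by 0.80 ± 0.16, whereas futB (slr0327) stood at 0.20 ± 0.13. For exbB1 (sll1404) the value was 1.01 ± 0.15, which passed, with 0.59 from its brightest probe, but its mean in 0Mn stayed below the mean floor of the controls. No gene of the isi operon passed (median -0.10, camera adjusted p = 0.556), and this median was positive under 4 other scalings, at 0.10 to 0.20. isiA (sll0247) stood at 0.47 ± 0.25 (adjusted p = 0.22), its antisense RNA IsrR at -0.01 ± 0.35, and isiB was at background in both groups. mrgA (slr1894) rose by 0.56 ± 0.17, and bfrA (sll1341) and bfrB (slr1890) stood at 0.50 ± 0.17 and 0.41 ± 0.13 (iron storage list, median 0.50, camera adjusted p = 0.0585). Iron-sulfur cluster assembly rose in 3 of 11 genes, sufD (slr0076) by 1.23 ± 0.12, sufC (slr0075) by 1.04 ± 0.18 and sufS (slr0077) by 0.80 ± 0.11 (median 0.07, camera adjusted p = 0.130). None of 7 metal-responsive regulators passed (median -0.07, or 0.02 with normexp and the 75th percentile, camera adjusted p = 0.494). Superoxide dismutase sodB (slr1516) stood at 0.61 ± 0.22 (adjusted p = 0.092).

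Inorganic carbon uptake fell in 13 of 14 genes in 0Mn (median -2.95, camera adjusted p = 6.07e-09; adjusted p = 0.336 with an estimated correlation). sll0218 fell by 5.54 ± 1.31 (-3.33 by its brightest probe, adjusted p = 0.062) and flv4 (sll0217) fell by 4.29 ± 1.09 (-4.02 by its brightest probe), both with a mean below the floor in 0Mn. sbtB (slr1513) fell by 3.38 ± 0.51, and cmpB (slr0041) was at background in 0Mn and at least 6.10-fold lower. With cmpB at that bound the list median was -2.64. Carbon fixation and carboxysome genes had a median of -0.25 (camera adjusted p = 0.0124; adjusted p = 0.336 with an estimated correlation), and rbcS (slr0012) fell by 0.58 ± 0.13 as the single member that passed over all genes. In nitrogen assimilation 5 of 13 genes rose, among them nrtB (sll1451) by 2.40 ± 0.44 and nrtC (sll1452) by 1.66 ± 0.34 (median 0.87, camera adjusted p = 0.0686). Further rises by size were ssl2814 (3.48 ± 0.49), slr1667 (3.21 ± 0.31) and sll0834 (2.59 ± 0.23), and further falls were sll0450 (3.36 ± 0.24, above background on 1 of 2 0Mn arrays) and slr0042 (3.31 ± 0.50). Among other transcripts slr1667-int2 rose by 3.40 ± 0.31, slr1667-5'UTR 8.55-fold, slr1295-int1 by 3.06 ± 0.18 and sll1454-int2, at background in the controls, at least 10.04-fold. us29-0-x fell by 6.43 ± 0.98, slr0616-int1 by 3.84 ± 0.55 and sll0450-5'UTR by 3.80 ± 0.25, and slr0040-int1, at background in 0Mn, was at least 9.06-fold lower.

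In total 492 genes (14.8%) passed in 0Mn against control, 349 higher and 143 lower, of which 92 and 34 changed at least 2-fold, and 724 other transcripts passed. Adjusted over the list alone, the counts were 17 higher for photosystem II, 11 higher and 1 lower for the phycobilisome, 7 higher for cytochrome b6f, 12 higher for tetrapyrrole synthesis and 4 higher for photosystem I and for ATP synthase. They were 3 lower for carbon fixation, 3 higher for iron storage, 3 higher and 1 lower for manganese uptake and 5 higher and 2 lower for nitrogen assimilation. No slide held both groups. With the slide as a block, estimated through the other groups, 327 genes passed, 211 of them in the main set, and 16 of 71 calls on named genes ended. The blocked list medians were 4.32 for manganese uptake, 0.54 for iron uptake, 0.76 for photosystem II and 1.45 for the extrinsic proteins. They were 0.75 for the phycobilisome, 0.40 for cytochrome b6f, 0.53 for tetrapyrrole synthesis, 0.59 for photosystem I, 0.57 for ATP synthase, -0.47 for carbon fixation and -4.58 for inorganic carbon uptake. The calls on futA1 (0.76, adjusted p = 0.053), exbB1 (1.02, adjusted p = 0.052), futC (0.58), feoB (0.53), psaB (0.60), petE (0.40), sufC (0.95) and cpcG2 (-0.69) ended with this block. The count was 101 without 0Mn 2, 249 without control 1, 255 without control 2 and 795 without 0Fe 1. Without 0Mn 2, 32 of the 71 calls on named genes ended, among them those on nrtD, nrtC, flv2, flv4, futC and feoB.

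The third comparison asked which transcripts changed when both metals were withheld. isiA (sll0247), near the floor in the controls, rose by 8.13 ± 0.25 (limma, adjusted p = 3.6e-08, n = 2 and 3). The receptor gene sll1206, below the floor in the controls, rose by 7.29 ± 0.23 (limma, adjusted p = 3.6e-08), or by 5.34 with its brightest probe. The manganese transporter genes mntC (sll1598), mntA (sll1599) and mntB (sll1600) rose by 3.87 ± 0.17, 3.22 ± 0.19 and 3.17 ± 0.15, but the brightest probe of mntB gave 0.70 (adjusted p = 0.093). IsrR fell by 7.13 ± 0.35, chlL (slr0749) by 3.68 ± 0.24 and the photosystem I gene psaF (sll0819) by 3.14 ± 0.13.

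All 4 isi genes rose in 0Fe0Mn (median 6.15, camera adjusted p = 4.76e-06; adjusted p = 0.0912 with an estimated correlation). isiB (sll0248) rose at least 40.6-fold above the control background, and with isiB at that bound the median was 5.18. Of 22 iron uptake genes 16 rose (median 2.01, camera adjusted p = 3.44e-11; adjusted p = 0.0912 with an estimated correlation). exbB1 (sll1404), below the floor in the controls, rose by 5.89 ± 0.15 (3.68 by its brightest probe), tonB (slr1484) by 4.09 ± 0.13 and feoB (slr1392) by 3.44 ± 0.16. futA2 (slr0513) rose by 3.36 ± 0.18, futA1 (slr1295) by 2.82 ± 0.13, futC (sll1878) by 2.09 ± 0.15 and futB (slr0327) by 0.39 ± 0.13. Manganese uptake and sensing rose in 4 of 5 genes (median 3.17, camera adjusted p = 0.000265; adjusted p = 0.291 with an estimated correlation). manS (slr0640) rose by 0.36 ± 0.12, or stood at -0.24 by its brightest probe and -0.10 with normexp and the 75th percentile, and manR (slr1837) stood at 0.45 ± 0.17 (adjusted p = 0.058). Both bacterioferritin genes fell, bfrA (sll1341) by 0.88 ± 0.17 and bfrB (slr1890) by 0.43 ± 0.13, whereas mrgA (slr1894) rose by 0.73 ± 0.17 (iron storage list, median -0.43, camera adjusted p = 0.556). Among 7 regulators fur (sll0567), sufR (sll0088) and manS rose, and pfsR (sll1392) fell (median 0.36, camera adjusted p = 0.197). Iron-sulfur cluster assembly rose in 7 of 11 genes, sufB (slr0074) by 1.64 ± 0.16 (median 0.43, camera adjusted p = 0.00160; adjusted p = 0.410 with an estimated correlation).

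Photosystem I fell in 12 of 12 genes in 0Fe0Mn (median -1.26, camera adjusted p = 1.27e-08; adjusted p = 0.291 with an estimated correlation). psaB (slr1835) fell by 2.06 ± 0.19 and psaA (slr1834) by 1.68 ± 0.19. Photosystem II fell in 17 of 23 genes (median -0.96, camera adjusted p = 2.47e-05; adjusted p = 0.411 with an estimated correlation). psbC (sll0851) fell by 2.33 ± 0.20 and psbD2 (slr0927) by 2.16 ± 0.33, and psbZ (sll1281, 1.28) and psbY (sml0007, 0.65) rose, named after their values were seen. The extrinsic proteins fell in 4 of 5 genes, psbO (sll0427) by 2.15 ± 0.13 (median -1.37, camera adjusted p = 0.000549; adjusted p = 0.291 with an estimated correlation). Phycobilisome genes fell in 12 of 13 cases, cpcD (ssl3093) by 3.15 ± 0.12 (median -1.52, camera adjusted p = 3.78e-09; adjusted p = 0.291 with an estimated correlation). In cytochrome b6f and electron carriers 6 of 11 genes fell, petF (ssl0020) by 1.99 ± 0.16 (median -0.44, camera adjusted p = 0.000216; adjusted p = 0.303 with an estimated correlation), and petJ (sll1796) stood at -0.35 ± 0.23. ATP synthase fell in 7 of 9 genes, atpI (sll1322) by 2.10 ± 0.12, and atpE (slr1330) rose by 0.56, named after its value was seen (median -0.95, camera adjusted p = 0.00250; adjusted p = 0.523 with an estimated correlation). Carbon fixation fell in 8 of 8 genes, rbcS (slr0012) by 1.85 ± 0.13 (median -1.32, camera adjusted p = 4.76e-06; adjusted p = 0.217 with an estimated correlation). Inorganic carbon uptake fell in 7 of 14 genes, sbtA (slr1512) by 2.48 ± 0.60 (median -2.05, camera adjusted p = 0.00414; adjusted p = 0.584 with an estimated correlation). Tetrapyrrole synthesis fell in 9 of 22 genes and rose in 3, which were chlD (slr1777, 0.82), hemE (slr0536, 0.64) and chlG (slr0056, 0.61), named after their values were seen (median -0.22, camera adjusted p = 0.0488; adjusted p = 0.612 with an estimated correlation). In nitrogen assimilation glnA (slr1756) rose by 1.09 ± 0.28, and amt1 (sll0108) and narB (sll1454) fell by 1.41 ± 0.39 and 0.73 ± 0.25 (median -0.31, camera adjusted p = 0.601). Superoxide dismutase sodB (slr1516) stood at -0.45 ± 0.22 (adjusted p = 0.13).

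The remaining large changes in 0Fe0Mn included a rise of sll1549 by 4.97 ± 0.18 and of exbD1 (sll1405), at background in the controls, at least 11-fold. isiC (sll0249) and slr1485, below the floor in the controls, rose by 5.01 ± 0.15 and 4.73 ± 0.20 (0.98 and 2.55 by the brightest probe). Falls were seen for slr1634 (5.38 ± 0.19), sll0450 (3.58 ± 0.24), sll0543 (3.26 ± 0.11), cmpB (slr0041, 3.81 ± 1.13, above background on 1 of 2 arrays) and sll1240, which was at background and at least 2.28-fold lower. sll0783 and ssr1251, below the floor in 0Fe0Mn, fell by 3.48 ± 0.36 and 3.33 ± 0.36 (-1.82 and -2.18 by the brightest probe). In other transcripts slr1489-5'UTR rose at least 125.7-fold, IsiA-2-0-x by 6.64 ± 0.17, IsiA-1-0-x by 6.42 ± 0.21 and isiA-0-x by 6.11 ± 0.16, and sll0247-as2 fell by 6.53 ± 0.30, slr1634-0-x by 6.12 ± 0.30 and NC-1103 fell by 5.32 ± 0.19. The 3 ribosomal RNA features fell, by 0.76, 0.90 and 0.82 (adjusted p = 0.0430, 0.0255 and 0.0364), and 30 of 42 transfer RNAs fell (median -0.79), alongside the falls of the photosynthesis lists.

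In total 1373 genes (41.4%) passed in 0Fe0Mn against control, 662 higher and 711 lower, of which 158 and 210 changed at least 2-fold, and 1910 other transcripts passed. Adjusted over the list alone, the counts were 5 higher for manganese uptake, 4 higher and 1 lower for the regulators, 5 lower for the extrinsic proteins, 8 lower for cytochrome b6f, 8 lower for inorganic carbon uptake and 1 higher and 1 lower for nitrogen assimilation. No slide held both groups. With the slide as a block 555 genes passed, 501 of them in the main set, and 17 of the 1373 changed sign. The block ended 29 of 100 calls on named genes, among them bfrA (-0.89, adjusted p = 0.093), bfrB (-0.09), narB (-0.02), glnA (1.46), sufR (0.61), manS (0.67), futB (0.41), cmpB (-5.71), mrgA (0.68), amt1 (-1.37) and pfsR (-0.39). List medians with that block were 6.52 for isi, 2.22 for iron uptake, 3.25 for manganese uptake, and 0.39 for iron-sulfur assembly. They were -0.86 for photosystem I, -0.66 for photosystem II, -0.89 for the extrinsic proteins and for the phycobilisome, -0.42 for cytochrome b6f, -0.85 for ATP synthase, -1.39 for carbon fixation and -3.90 for inorganic carbon uptake. Tetrapyrrole synthesis (-0.14) no longer passed. The count was 725 without 0Fe0Mn 1 and 770 without 0Fe0Mn 2. Leaving out a single array ended 21 of the 100 calls in at least 1 case, among them sbtA, bfrB, glnA and narB.

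**Figure D3:**
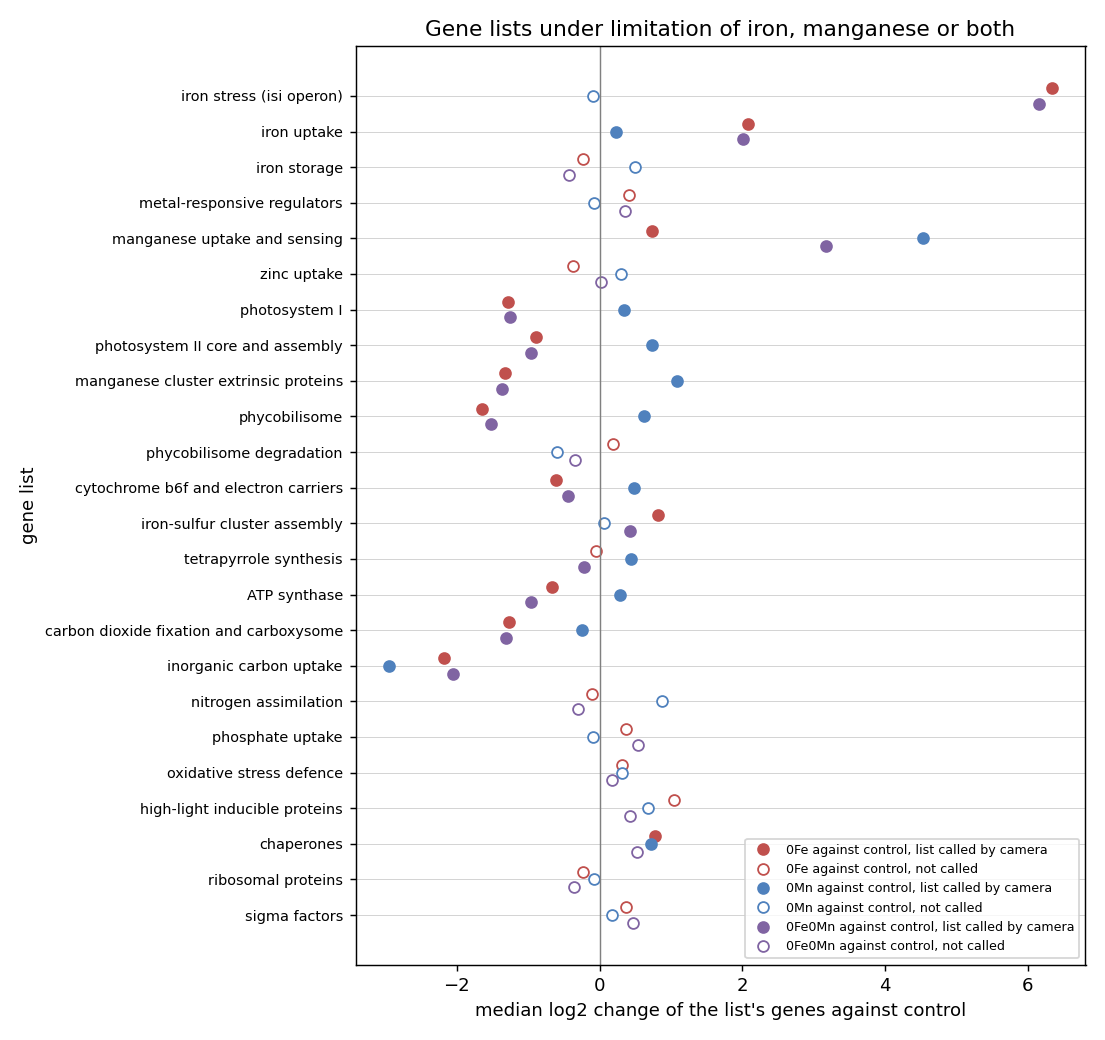
Median log2 change of each of 24 gene lists against control in 0Fe, 0Mn and 0Fe0Mn; filled points are lists that passed with camera at its preset correlation, open points lists that did not. The isi operon lies highest in both groups without iron, and the photosystem, phycobilisome and cytochrome lists lie below 0 in those groups and above 0 in 0Mn.

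Between 0Fe and 0Fe0Mn, which differed in manganese, 3 genes passed. mntB (sll1600) rose by 2.44 ± 0.15, mntA (sll1599) by 2.40 ± 0.19 and mntC (sll1598) by 2.21 ± 0.17 (limma, adjusted p = 0.00024, 0.00059 and 0.00059, n = 2 and 3), but the brightest probe of mntB alone, at 1.75, did not pass (adjusted p = 0.34). All 3 also rose in 0Mn against control. Manganese uptake and sensing was the single list that rose (3 of 5 genes, median 2.21, camera adjusted p = 2.15e-06; adjusted p = 0.217 with an estimated correlation), with manS (slr0640) at -0.06 ± 0.12 and manR (slr1837) at -0.29 ± 0.17. No member of another list passed on its own. isiA (sll0247) stood at -0.65 ± 0.25 and isiB (sll0248) at -0.33 ± 0.18. futA2 (slr0513) stood at -0.35 ± 0.18, futA1 (slr1295) at -0.32 ± 0.13, futC (sll1878) at -0.18 ± 0.15, futB (slr0327) at -0.04 ± 0.13 and feoB (slr1392) at -0.25 ± 0.16. bfrA (sll1341) and bfrB (slr1890) stood at -0.48 ± 0.17 and -0.19 ± 0.13. psbO (sll0427) stood at -0.15 ± 0.13, psaA (slr1834) at -0.48 ± 0.19 and psaB (slr1835) at -0.32 ± 0.19. petF (ssl0020) stood at -0.26 ± 0.16, petJ (sll1796) at 0.29 ± 0.23, sodB (slr1516) at -0.27 ± 0.22 and IsrR at 0.42 ± 0.35. None of these genes passed, with isiA and IsrR at adjusted p = 0.51 and 0.62. As lists, 6 were lower at the preset correlation: iron uptake (median -0.17, camera adjusted p = 0.00417), chaperones (-0.41, 0.00681), tetrapyrrole synthesis (-0.17, 0.0170), ATP synthase (-0.22, 0.0293), iron storage (-0.34, 0.0334) and oxidative stress defence (-0.28, 0.0393). With an estimated correlation their adjusted p was 0.317, 0.443, 0.583, 0.605, 0.412 and 0.362.

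Of 3319 genes 349 had an unadjusted p under 0.05 in 0Fe0Mn against 0Fe, and of the other transcripts 0 passed in limma, with 463 at an unadjusted p under 0.05; no other tool was run. Each list's count was the same when adjusted over the list alone. No slide held both groups. With the slide as a block 16 genes passed, the 3 mnt genes among them. Blocked list medians were 2.51 for manganese uptake, -0.46 for chaperones and -0.35 for ATP synthase, while iron uptake (-0.07), iron storage, tetrapyrrole synthesis and oxidative stress defence no longer passed. The count was 254 without 0Fe 1.

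The 0Fe0Mn medium differed from 0Mn in iron and held the siderophore, which is not stated for 0Mn. Between 0Mn and 0Fe0Mn isiA (sll0247) rose by 7.66 ± 0.27 and isiC (sll0249) by 5.23 ± 0.17 (limma, adjusted p = 1.5e-07 and 8.6e-08, n = 2 and 2). Against control the brightest probe of isiC gave 0.98 in 0Fe0Mn and -0.42 in 0Mn, so the size of its rise here is uncertain. sll1206, below the floor in 0Mn, rose by 7.44 ± 0.25 (adjusted p = 1.1e-07; 5.26 by its brightest probe). Of the photosystem II genes psbD2 (slr0927) fell by 4.94 ± 0.36 and psbO (sll0427) fell by 3.32 ± 0.15. The Mnt transporter genes were lower than in 0Mn, mntB (sll1600) by -1.51 ± 0.17, mntA (sll1599) by -1.32 ± 0.20 and mntC (sll1598) by -0.69 ± 0.19. By its brightest probe mntC stood at -0.23 and did not pass.

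All 4 isi genes rose against 0Mn (median 6.25, camera adjusted p = 4.76e-06; adjusted p = 0.0912 with an estimated correlation); isiB (sll0248) rose at least 49.5-fold above the 0Mn background, and with isiB at that bound the median was 5.43. Iron uptake rose in 15 of 22 genes (median 1.60, camera adjusted p = 3.78e-09; adjusted p = 0.103 with an estimated correlation). exbB1 (sll1404) rose by 4.89 ± 0.17, feoB (slr1392) by 2.64 ± 0.17, futA1 (slr1295) by 1.85 ± 0.14, futA2 (slr0513) by 1.69 ± 0.20 and futC (sll1878) by 1.18 ± 0.17, and futB (slr0327) stood at 0.19 ± 0.14. The size for exbB1 is uncertain, since its brightest probe gave 3.68 in 0Fe0Mn and 0.59 in 0Mn, each against control. IsrR fell by 7.12 ± 0.38, bfrA (sll1341) by 1.37 ± 0.19, bfrB (slr1890) by 0.84 ± 0.15 and sodB (slr1516) by 1.06 ± 0.24. By means over probes the regulator genes fur (sll0567), manR (slr1837), sufR (sll0088) and manS (slr0640) rose, by 2.07 ± 0.16, 0.89 ± 0.18, 0.92 and 0.43 ± 0.13. The brightest probe of manS gave -0.64, which passed as lower, and normexp with the 75th percentile -0.12, so its direction stays open. The regulator list had a median of 0.43, or -0.12 with normexp and the 75th percentile (camera adjusted p = 0.186). By means over probes manganese uptake and sensing had 2 genes higher, manS among them, and 3 lower (median -0.69, camera adjusted p = 0.446).

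All 12 photosystem I genes fell against 0Mn (median -1.59, camera adjusted p = 1.63e-08; adjusted p = 0.291 with an estimated correlation). psaB (slr1835) fell by 2.73 ± 0.21 and psaA (slr1834) by 1.99 ± 0.20. Photosystem II fell in 17 of 23 genes (median -1.58, camera adjusted p = 1.68e-08; adjusted p = 0.317 with an estimated correlation). psbD (sll0849) fell by 4.23 and psbC (sll0851) fell by 3.91, and psbZ (sll1281, 0.86) rose, named after its value was seen. The extrinsic proteins fell in 4 of 5 genes (median -1.98, camera adjusted p = 0.000110; adjusted p = 0.291 with an estimated correlation), and the phycobilisome in 12 of 13 (median -2.21, camera adjusted p = 1.02e-09; adjusted p = 0.291 with an estimated correlation). Cytochrome b6f and electron carriers fell in 10 of 11 genes, petB (slr0342) by 3.22 and petF (ssl0020) by 2.14 ± 0.17 (median -1.03, camera adjusted p = 2.05e-06; adjusted p = 0.291 with an estimated correlation), and petJ (sll1796) stood at -0.33 ± 0.25. ATP synthase fell in 8 of 9 genes, atpI (sll1322) by 2.29 (median -1.27, camera adjusted p = 7.42e-05; adjusted p = 0.411 with an estimated correlation), and carbon fixation in 7 of 8 (median -1.02, camera adjusted p = 0.000178; adjusted p = 0.291 with an estimated correlation). Tetrapyrrole synthesis fell in 12 of 22 genes, chlA2 (sll1874), below the floor in 0Fe0Mn, by 4.80 ± 0.25 (-2.78 by its brightest probe) and chlL (slr0749) by 4.73 (median -0.97, camera adjusted p = 0.000786; adjusted p = 0.443 with an estimated correlation). chlG (slr0056, 0.82) and chlD (slr1777, 0.64) rose, named after their values were seen. Inorganic carbon uptake was the single list of this set that was higher, with cmpC (slr0043), below the floor in 0Mn, up by 1.27 (0.65 by its brightest probe, adjusted p = 0.12) as the member that passed (median 1.20, camera adjusted p = 0.0445; adjusted p = 0.653 with an estimated correlation). In nitrogen assimilation 5 of 13 genes fell, narB (sll1454) by 3.31 and nrtD (sll1453) by 3.22, and ntcA (sll1423) rose by 0.57, named after its value was seen (median -0.27, or 0.03 to 0.26 under 3 other scalings, camera adjusted p = 0.136). slr1634 fell by 5.49 ± 0.20 and ssl2814 by 4.89 ± 0.53, ssr1251, below the floor in 0Fe0Mn, fell by 4.98 ± 0.39 (-3.19 by its brightest probe), and all 3 ribosomal RNA features and 34 of 42 transfer RNAs fell beside the photosynthesis lists.

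In total 1405 genes (42.3%) passed in 0Fe0Mn against 0Mn, 601 higher and 804 lower, of which 158 and 349 changed at least 2-fold, and 1973 other transcripts passed. Adjusted over the list alone, the counts were 18 lower for photosystem II, 13 lower for tetrapyrrole synthesis, 8 lower for carbon fixation, 4 higher and 1 lower for the regulators and 0 for inorganic carbon uptake. On slide 3, which held 0Mn 3 and both 0Fe0Mn arrays and whose contrast equals the slide-blocked estimate, isiA rose by 7.61. The block passed 1538 genes, 1261 of them in the main set. Its list medians were 6.42 for isi, 1.63 for iron uptake and -1.38 for photosystem I, and -1.30 for photosystem II, -1.89 for the extrinsic proteins and -2.14 for the phycobilisome. They were -0.996 for cytochrome b6f, -1.43 for ATP synthase, -0.98 for carbon fixation, -0.80 for tetrapyrrole synthesis and 1.28 for inorganic carbon uptake. The count was 855 without 0Fe0Mn 1 and 919 without 0Fe0Mn 2. Leaving out a single array ended 13 of 84 calls on named genes in at least 1 case, mntC, manS, cmpC and sodB among them.

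Whether the effect of one metal depended on the other was tested as the interaction, the change from 0Fe to 0Fe0Mn minus the change from control to 0Mn (limma, n = 3, 3, 2 and 2). By means over probes the manganese transporter genes rose less without iron than with it: the interaction was -2.35 ± 0.24 for mntC (sll1598), -2.25 ± 0.22 for mntB (sll1600) and -2.14 ± 0.26 for mntA (sll1599), each with adjusted p of at most 0.0057. By the brightest probe mntA held, at -1.99 (adjusted p = 0.012), but mntC at -1.17 (adjusted p = 0.054) and mntB at -0.0738 did not pass. psbD2 (slr0927) had an interaction of -3.39 ± 0.46 and psbO (sll0427) one of -1.32 ± 0.19, since both rose in 0Mn and neither passed between 0Fe and 0Fe0Mn. The calls on psbD2 and psbO ended when 0Fe0Mn 1 was left out. For the bicarbonate transporter gene sbtA (slr1512) it was 3.88 ± 0.85 (adjusted p = 0.032), a call that ended when any single control array was left out.

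Among iron uptake genes futA2 (slr0513) had an interaction of -2.02 ± 0.26, futA1 (slr1295) of -1.29 ± 0.18, futC (sll1878) of -1.09 ± 0.21, feoB (slr1392) of -1.05 ± 0.22 and exbB1 (sll1404) of -1.33 ± 0.21. Of 22 members 8 passed, all lower (median -0.52, camera adjusted p = 2.47e-05; adjusted p = 0.272 with an estimated correlation). isiA (sll0247) stood at -1.12 ± 0.35 (adjusted p = 0.092), IsrR at 0.42 ± 0.49, bfrA (sll1341) at -0.98 ± 0.25, bfrB (slr1890) at -0.60 ± 0.19 and sodB (slr1516) at -0.87 ± 0.31, none of which passed. The iron storage list was lower as a list (median -0.91, camera adjusted p = 0.0189; adjusted p = 0.375 with an estimated correlation). Photosystem II was lower in 10 of 23 genes, psbD (sll0849) by -2.64 ± 0.30 and psbC (sll0851) by -2.14 ± 0.29 (median -0.67, camera adjusted p = 2.56e-08; adjusted p = 0.321 with an estimated correlation). The extrinsic proteins were lower in 4 of 5 (median -1.10, camera adjusted p = 0.000881; adjusted p = 0.291 with an estimated correlation). In the phycobilisome 4 of 13 genes were lower, apcA (slr2067), apcB (slr1986), apcF (slr1459) and cpcB (sll1577) (median -0.65, camera adjusted p = 0.00121; adjusted p = 0.443 with an estimated correlation). In cytochrome b6f 4 of 11 were lower, petB (slr0342) by -1.73 ± 0.22 (median -0.67, camera adjusted p = 0.000150; adjusted p = 0.303 with an estimated correlation). Tetrapyrrole synthesis was lower in 6 of 22, chlA2 (sll1874) by -2.18 ± 0.33 and ho2 (sll1875) by -2.02 ± 0.20 (median -0.63, camera adjusted p = 5.51e-06; adjusted p = 0.336 with an estimated correlation). psaF (sll0819), at -0.85 ± 0.19, was the photosystem I gene that passed (median -0.44, camera adjusted p = 0.0309; adjusted p = 0.584 with an estimated correlation). atpE (slr1330), at -0.73 ± 0.18, was the ATP synthase gene (median -0.52, camera adjusted p = 0.00213; adjusted p = 0.516 with an estimated correlation).

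Inorganic carbon uptake was higher in the interaction in 7 of 14 genes (median 3.36, camera adjusted p = 3.93e-08; adjusted p = 0.346 with an estimated correlation). Among them were sbtB (slr1513, 3.58 ± 0.72), cmpA (slr0040, 3.57 ± 0.84) and cupA (sll1734, 3.16 ± 0.67), a gene of inducible carbon dioxide uptake. Leaving out control 1 alone ended the calls on sbtB, cmpA and cupA. rbcS (slr0012), at 0.88 ± 0.19, was the carbon fixation gene that passed (median 0.26, camera adjusted p = 0.00864; adjusted p = 0.336 with an estimated correlation). In nitrogen assimilation nrtD (sll1453), nrtB (sll1451) and narB (sll1454) stood at -3.10 ± 0.66, -2.76 ± 0.63 and -2.67 ± 0.35 and passed (median -0.90, camera adjusted p = 0.0543). Iron-sulfur assembly was lower through sufD (slr0076), sufC (slr0075) and sufS (slr0077), at -1.32 ± 0.18, -1.22 ± 0.26 and -0.87 ± 0.16 (median -0.24, camera adjusted p = 0.0227; adjusted p = 0.523 with an estimated correlation). Manganese uptake and sensing was lower through its 3 transporter genes (median -2.14, camera adjusted p = 0.00501; adjusted p = 0.317 with an estimated correlation), of which mntA alone passed by its brightest probe. The isi list did not pass (median -0.10, camera adjusted p = 0.911). Further large interactions were ssl2814 (-4.26 ± 0.69), slr1667 (-2.67 ± 0.44) and slr0042 (3.70 ± 0.70). The calls on ssl2814, slr1667 and futA1 (slr1295) ended without 0Fe0Mn 1, and that on slr0042 without control 1.

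In total 215 genes passed in the interaction, 21 higher and 194 lower, and 228 other transcripts passed. Adjusted over the list alone, the counts were 11 lower for iron uptake, 3 for iron storage, 14 for photosystem II, 10 for the phycobilisome with 1 higher, and 7 for cytochrome b6f. They were 11 lower for tetrapyrrole synthesis, 2 for photosystem I, 5 for ATP synthase, 5 for nitrogen assimilation and 1 for isi, and 13 higher for inorganic carbon uptake and 3 for carbon fixation. With the slide as a block 155 genes passed, 95 of them in the main set. The calls on nrtB (-1.83), nrtD (-2.21), feoB (-0.92), futC (-0.77), sufC (-0.93), cpcB (-0.64) and ssl2814 (-3.24) ended, and so did that on the iron-sulfur assembly list (adjusted p = 0.646). The count was 22 without 0Fe0Mn 1, 39 without 0Fe0Mn 2, 64 without 0Mn 2, and 81 to 126 without a control array. It was 933 without 0Fe 1, 106 without 0Fe 2, 92 without 0Fe 3 and 605 without 0Mn 3. In at least 1 of these cases 38 of 48 calls on named genes ended, 36 of them without 0Fe0Mn 1. For exbB1, mntB, chlA2 and ho2 the mean of a group lay below the floor, so their interaction values are less certain than their standard errors say. The brightest probe of mntB (sll1600) gave an interaction of -0.0738 and that of mntC (sll1598) gave -1.17, neither of which passed.

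Across genes, which are not independent replicates, 641 genes rose and 579 fell in both 0Fe and 0Fe0Mn, against 194.3 and 182.5 were the calls independent, and 0 went opposite ways. Of the genes that rose in 0Mn 30.7% also rose in 0Fe, where 29.3% of all genes rose, 58 genes fell in both (36.71 were they independent), and 29 and 103 went opposite ways. These comparisons share their control arrays, which pulls their values together: the correlation across transcripts was 0.931 for 0Fe with 0Fe0Mn and 0.279 for 0Fe with 0Mn, where data simulated without any change gave 0.452 and 0.448. The covariances were 0.601 and 0.121, against 0.0215 and 0.0213 in the simulated data. Those data held no slide effect, although slides went with groups, so the excess does not tell a shared response from the slide. The effect of iron withheld with manganese and without it shares no array, and its correlation across transcripts was 0.685 (0.710 over genes, 0.765 with the slide as a block). Under that block, data simulated without any change gave -0.0002 (-0.049 to 0.054). The blocked iron effects rest on 0Fe 1 and on 0Mn 3 as the single arrays of their groups. The effect of manganese withheld with iron and without it correlated at -0.225 across transcripts, with a standard error of 0.249 from leaving out each array in turn. That correlation cannot be told from none. Under the slide block it was 0.556, but there the estimates share arrays, and data simulated without any change gave 0.515, so this value does not show a shared effect.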

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

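The tests of a wrong label, of the slide and of mixed RNA in this part were chosen after the results were seen; those of regrouped arrays, probe base composition and background subtraction were planned before. No test for single outlying samples was run, since the groups hold 2 or 3 arrays. The results below were picked out because the effect of a metal differed with the other metal in the interaction test.

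In that test 215 genes passed. Higher values were those of sbtA (slr1512, 3.88), slr0042 (3.70), sbtB (slr1513, 3.58), cmpA (slr0040, 3.57) and cupA (sll1734, 3.16), 4 of them in inorganic carbon uptake. Leaving out control 1 alone ended each of these calls. Lower values were those of ssl2814 (-4.26), psbD2 (slr0927, -3.39), nrtD (sll1453, -3.10), nrtB (sll1451, -2.76), slr1667 (-2.67) and psbO (sll0427, -1.32). The manganese transporter genes mntC (sll1598), mntB (sll1600) and mntA (sll1599) stood at -2.35, -2.25 and -2.14. By the brightest probe mntA passed at -1.99, whereas mntC at -1.17 and mntB at -0.0738 did not. The iron uptake genes futA2 (slr0513), futA1 (slr1295), futC (sll1878) and feoB (slr1392) stood at -2.02, -1.29, -1.09 and -1.05. With the slide as a block the calls on ssl2814, nrtD, nrtB, futC and feoB ended. Without control 1 those on nrtD, nrtB, futC and feoB ended as well. Without 0Fe0Mn 1 the calls on psbD2, psbO, slr1667, futA1 and ssl2814 ended too.

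The mnt genes were lower without both metals than without manganese alone, by a mean of -1.17 over mntC, mntA and mntB. With normexp and quantile normalization the mean was -0.986 (mean of the 3 standard errors 0.137), so the difference did not hang on the scanner software's subtraction alone. As normexp corrects for background too, this cannot exclude a part of background subtraction as such. A slide effect as the whole cause is argued against: on slide 3 alone the mean was -0.959, and all 3 genes passed with the slide as a block. The mean of the 3 standard errors, from the spread of all groups, was 0.145. Slide 3 held both 0Fe0Mn arrays and 1 0Mn array. By its brightest probe mntC (sll1598) stood at -0.23 from 0Mn and did not pass. With manganese present the lack of iron went the other way for mntC and mntA, as mntC rose by 1.66 ± 0.15 and mntA rose by 0.82 ± 0.17 in 0Fe. The direction of mntB (sll1600) in 0Fe stays open, at 0.74 by its mean over probes and -1.06 by its brightest probe. A biological cause stays open as a hypothesis and was not tested.

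Iron uptake genes rose in 0Mn while isiA (sll0247) did not pass. RNA of 0Fe cultures mixed into the 0Mn samples is argued against: the share needed ran from 1.08% for exbD1 (sll1405), a gene near background, to 23.1% for futC (sll1878). These shares would raise isiA by 2.52 and 6.68, and it stood at 0.47 (standard error 0.25). With the slide as a block the mean rise of the 10 genes that passed was 0.777 against 0.871, and 3 of the 10 passed. The mean of their standard errors in the blocked fit was 0.228. Among the calls that ended, the value fell from 0.91 ± 0.15 to 0.58 ± 0.20 for futC and from 0.80 ± 0.16 to 0.53 ± 0.26 for feoB. For exbB1 (sll1404) it went from 1.01 ± 0.15 to 1.02 ± 0.27, so its wider standard error ended the call. The 10 genes were picked by the fit without a block, which shares arrays with the blocked fit. Their mean therefore cannot decide whether the slide was the whole cause. The blocked estimate also rests on 0Mn 2 as the single 0Mn array on a slide with 0Fe. A response of iron uptake to the lack of manganese stays open as a hypothesis that was not tested.

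The array 0Fe 1 lay closer to the 0Fe0Mn arrays (r 0.992) than to 0Fe 2 and 0Fe 3 (r 0.970). A 0Fe0Mn sample under its label is argued against by the mnt genes, whose mean level in 0Fe 1 was -2.54 from the 0Fe0Mn mean (standard error 0.23). Hybridisation by base composition is argued against by a rho of 0.0162 between the GC share of 18003 probes and their difference. A batch shared with the slide fits: the difference of slide 2 from the other slide in 0Fe and that in 0Mn correlated at 0.653 across transcripts, which are not independent replicates. Whether that batch lies in the slide or in cultures processed together cannot be told apart, and a true difference between cultures was not tested.

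Regrouping the 3 control and 3 0Fe arrays gave as many genes as the 1826 of the real grouping in 1 of 10 splits, the real one, and 0 in the highest other; 10 splits are too few for a share under 0.05.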

How the results depend on the processing

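Of 460 named values, 409 passed in the main fit and 248 of these passed under every alternative; the sign turned for 10. Across named values and alternatives the label was the same in 10826 cases, weaker in 925, stronger in 85 and reversed in 15. Signals near background, groups of 2 arrays and slides that go with groups limit the data. The cause was not tested for any shift below.

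Sign turned as follows. In 0Fe sll1600 (mntB) stood at -0.18 in the deposited table and at -1.06 both with its brightest probe and with only probes well above background on all arrays, and the brightest probe gave -0.0545 for slr0640 (manS) and -0.15 for ssl0461. In 0Mn sll1796 (petJ) stood at 0.72 with its brightest probe. In 0Fe0Mn against control slr0640 stood at -0.10 with normexp and the 75th percentile and at -0.24 with the brightest probe, which gave -0.26 for sll0656. In 0Fe0Mn against 0Mn normexp and the 75th percentile gave -0.12 for slr0640 and -0.0381 for sll0656, and the brightest probe -0.64 for slr0640, -0.0461 for slr0387, -0.0439 for sll0656 and -0.16 for sll0654.

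Counts of genes that moved by over 1.5 times were as follows. In 0Mn (main 492) the count was 305 with the brightest probe, 327 with the slide as a fixed block and 311 with array weights. In 0Fe0Mn against control (1373) it was 555 with the slide as a fixed and 875 as a random block and 2210 with array weights. In 0Fe0Mn against 0Fe (3) it was 16 with the fixed slide block, 1114 with array weights, 790 without 0Fe 1 and 0Mn 2 and 5 without slide 2. In the interaction (215) it was 124 with the deposited table, 69 with the brightest probe, 888 with array weights, 630 without 0Fe 1 and 0Mn 2 and 123 without slide 2. The array weights were lowest for 0Fe 1 (0.210) and highest for both 0Fe0Mn arrays (2.60). The fit to only the arrays compared does not apply to the interaction, which uses all groups.

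Whether replicate numbers pair the arrays cannot be decided here. Deviations of 12 same-number pairs had a median r of -0.05, against 0.04 in 25 pairs of different number. They ran from -0.60 (0Fe 3 with 0Mn 3) to 0.45 (0Fe 2 with 0Mn 2, which shared slide 2). Deviations cancel within a group, which fixes part of these values in advance. With the replicate block the counts were 1736 in 0Fe, 296 in 0Mn, 1194 in 0Fe0Mn, 3 against 0Fe, 1129 against 0Mn and 63 in the interaction.

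Leaving out a single array gave 1487 to 2016 genes in 0Fe, 101 to 795 in 0Mn, 725 to 1625 in 0Fe0Mn, 3 to 254 against 0Fe, 855 to 1616 against 0Mn and 22 to 933 in the interaction. A lone array left in 0Mn or 0Fe0Mn was assumed to vary like the other groups. The correlation across transcripts of the iron effect with and without manganese ran from 0.563 to 0.776, and that of the manganese effect with and without iron from -0.353 to -0.00149, with 0.556 under the fixed slide block, where the estimates share arrays and unchanged data gave 0.515.

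With normexp and the 75th percentile the median over genes shifted by -0.11 in 0Fe, -0.10 in 0Fe0Mn and -0.13 against 0Mn. Genes then split into 664 higher and 1016 lower in 0Fe (main 974 and 852), 428 and 902 in 0Fe0Mn (662 and 711) and 321 and 912 against 0Mn (601 and 804). The deposited table split 0Fe into 734 and 1092 and shifted the interaction by 0.13, and normexp with quantile normalization shifted it by 0.11.

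Of 144 tests of a list 71 passed with camera at the preset correlation and 0 with an estimated correlation. Of the other tests fry passed 77, 61 of them shared, the slide block 75, 61 shared, and none turned direction.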

Other observations

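Chaperones rose in 5 of 9 genes in 0Fe (median 0.77, camera adjusted p = 0.0189; adjusted p = 0.523 with an estimated correlation) and in 3 in 0Mn (median 0.72, camera adjusted p = 0.00639; adjusted p = 0.443 with an estimated correlation). Neither passed with the slide as a block, where the medians were 0.64 and 0.37 (adjusted p = 0.0799 and 0.406). hspA (sll1514), a small heat shock protein gene, rose by 1.37 ± 0.19 in 0Fe and 0.96 in 0Mn. In 0Fe0Mn 4 chaperone genes rose and htpG (sll0430) fell by 0.95 (median 0.52, camera adjusted p = 0.162). In the interaction chaperones were lower as a list (median -1.06, camera adjusted p = 0.00114; adjusted p = 0.409 with an estimated correlation). Oxidative stress defence was lower too (median -0.59, camera adjusted p = 0.0254; adjusted p = 0.336 with an estimated correlation), but not with the slide as a block (adjusted p = 0.0645). Sigma factor genes rose in 5 of 9 cases in 0Fe, sigE (sll1689) by 1.10 ± 0.11 and sigB (sll0306) by 0.94, while sigI (sll0687), named after its value was seen, fell by 0.51 (median 0.37, camera adjusted p = 0.187). In 0Mn sigF (slr1564) rose by 0.83 and sigE fell by 0.57 (median 0.17, camera adjusted p = 0.738), and in 0Fe0Mn 5 rose and sigI fell by 0.65 (median 0.47, camera adjusted p = 0.450). The counts adjusted over the list alone were 6 and 8 higher, the latter with 1 lower, for chaperones in 0Fe and 0Mn, and 1 higher and 2 lower and 5 higher and 3 lower for sigma factors in 0Mn and 0Fe0Mn. For 0Fe0Mn chaperones they were 5 higher and 1 lower.

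Ribosomal protein genes went both ways, with rplJ (sll1745) and rplL (sll1746) down by 1.63 ± 0.19 and 1.59 ± 0.18 in 0Fe and rpsJ (sll1101) up by 0.65 (30 genes, 7 higher and 3 lower, median -0.24, camera adjusted p = 0.574). In 0Mn rpsJ and rpsG (sll1097) rose (median -0.08, mean 0.0346, camera adjusted p = 0.690). In 0Fe0Mn 5 rose and 4 fell (median -0.35, camera adjusted p = 0.343). Phosphate uptake rose in 3 of 8 genes in 0Fe (median 0.37, camera adjusted p = 0.146), pstB (sll0683), pstA (sll0682) and pstC (sll0681), and in 5 in 0Fe0Mn (median 0.54, camera adjusted p = 0.0582), phoA (sll0654) by 0.82. In 0Mn pstA was the single one that rose (median -0.08, or 0.02 with normexp and the 75th percentile, camera adjusted p = 0.745). High-light inducible genes hliA (ssl2542) and hliD (ssr1789) rose in 0Fe by 1.16 ± 0.30 and 0.94 ± 0.20 (4 genes, median 1.04, camera adjusted p = 0.150), and hliA rose in 0Fe0Mn by 0.99. On slide 1 alone hliA and hliD stood at 0.68 and 0.47 in 0Fe, and hliB (ssr2595) and hliC (ssl1633) at -0.49 and -0.33. The list stood at 0.68 in 0Mn and 0.43 in 0Fe0Mn (camera adjusted p = 0.217 and 0.403). Oxidative stress defence rose in 3 of 8 genes in 0Fe, gpx2 (slr1992), sll1621 and tpx (sll0755), with a median of 0.31 (camera adjusted p = 0.201), and 0 passed in 0Mn or 0Fe0Mn (medians 0.31 and 0.18, camera adjusted p = 0.0987 and 0.729). The phycobilisome degradation genes nblA1 (ssl0452) and nblA2 (ssl0453) stood at 0.33 and 0.05 in 0Fe, -0.54 and -0.67 in 0Mn and -0.16 and -0.52 in 0Fe0Mn, none passing (camera adjusted p = 0.888, 0.287 and 0.658). In zinc uptake znuB (slr2045) fell by 0.80 in 0Fe and 0.72 in 0Fe0Mn. The 3 genes had medians of -0.37, 0.30 and 0.03 in 0Fe, 0Mn and 0Fe0Mn (camera adjusted p = 0.308, 0.896 and 0.483), the last -0.01 with quantile normalization and with a mean of -0.219. When adjusted over the list alone, 1 zinc uptake gene was higher and 1 lower in 0Mn, pstA did not pass in 0Mn, hliA did not pass in 0Fe0Mn, and the other counts of this paragraph held but for 1 ribosomal protein gene in 0Mn. Calls that ended with the slide as a block included hliA (0.68), gpx2 (0.32), sll1621 (0.41) and pstA (0.28) in 0Fe. They also included rpsG (0.53) and pstA (0.25) in 0Mn, and hliA (0.59), phoA (1.15) and znuB (-0.56) in 0Fe0Mn.

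Antisense transcripts numbered 413 higher and 427 lower in 0Fe, 49 and 121 in 0Mn and 346 and 187 in 0Fe0Mn, of 1671 tested. Of 688 5' untranslated regions 216 rose and 136 fell in 0Fe, and across 683 pairs their changes went with those of the gene downstream (rho 0.637 in 0Fe, 0.615 in 0Mn). It was asked, before the data were examined, whether antisense transcripts move against their genes, as IsrR does against isiA. Across 1650 pairs, which are not independent replicates, rho was 0.0243 in 0Fe (10000 permutations, p = 0.30), which argues against opposition in most pairs, although Pearson's r was -0.0841, with 192 opposite and 232 same-way pairs where both passed. In 0Mn rho was -0.0713 (p = 0.003), with 33 pairs where both passed, 20 of them opposite. That was below 0 but short of the bound set beforehand, so the question stays open for 0Mn.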
